A study of Mus musculus with 28 samples.

How the data were processed

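Histone acetylation was measured by chromatin immunoprecipitation and sequencing in mouse lung adenocarcinoma cells. The 28 samples of the series were 24 immunoprecipitated libraries and 4 input libraries. For each of 2 marks, acetylated lysine 27 of histone H3 (H3K27ac) and acetylated lysine 9 (H3K9ac), there were 4 groups of 3 libraries, which the labels call biological replicates. The groups were cells sensitive to PD-1 blockade (Sen), resistant cells (Res), resistant cells with a control short hairpin RNA (Res_Ctrl) and resistant cells with a hairpin against Fabp7 (Res_shFabp7). Peak lists of the 24 immunoprecipitated libraries were analysed, and values of the 4 inputs were not used here. Per the labels, cells were fixed in 1% formaldehyde for 10 minutes and libraries were read as single 50-base reads, with 53 to 158 M reads per sample.

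Reads were aligned with Bowtie 1.1.2 and peaks were called with MACS 1.4.2 on the mouse genome build mm10, in so far as the submitters' processing notes name these tools and this build. The authors deposited 1 peak list per library, so peaks were called in each library alone. Whether the inputs served as the caller's control, and how duplicate reads and excluded regions were treated, was not given in the sources used here. Each deposited peak has a tag count, which is a whole number not scaled to the library's reads. The deposited score of a peak is -10 times the log10 of its p-value; the lowest score was 50.0, a p of 1e-05. The deposited fold of a peak is the authors' ratio of its tags to the background that MACS estimated, and was used only to describe peaks within a list. Peak numbers within each list ran without gaps.

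The 24 lists held 447697 peaks, from 11771 to 28934 per library, and 2.24 to 11.5 M tags in peaks per library. The total reads of each library were not in the lists, and tags in peaks are not sequencing depth, because they grow with the length that was called. Of the 24 pairs of lists of the same group and mark none was identical, and at most 0.01% of intervals recurred exactly within a pair. Every library therefore counted as 1 replicate. Lists of different groups were not compared in this way.

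For each comparison and mark, peaks of the 6 libraries that overlapped by 1 base or more were merged into regions. A region was gained where all 3 libraries of the first group and 0 of the second had a peak, and lost in the reverse case. Fisher's exact test per region cannot pass 0.05 with 3 libraries against 3, so gained and lost regions have no p-value each. Regions with a peak in all 6 libraries were tested for changed tag counts with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), TMM scaling and Benjamini-Hochberg adjustment at 0.05. A region without a peak in a library has no deposited count, so a site absent from a group could enter only as gained or lost. Changes are log2 ratios of the first group to the second, with the standard error of the fit, and each rests on 3 libraries against 3. Levels are CPM, TMM-scaled and relative to the tags in the tested regions, as mean ± SD over 3 libraries. Numbers of peaks were compared with two-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1.

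Coordinates are 1-based positions on mm10. Genes were the 21887 protein-coding genes of the matching RefSeq table, which gives each gene's outer ends but neither strand nor transcripts. A gene was therefore assigned the regions within 1 kb of either annotated end, in place of the planned promoters, and whether a named region lies over an exon or an intron is not given. The tested region of a gene was the one with the highest mean scaled tags; genes that share a region are named together.

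The 24 gene lists, with 593 entries, were written before the data were examined, as were the groups, the tests, the rule for named genes and most alternatives. They were fatty acid binding proteins, fatty acid uptake and PPAR signalling, fatty acid synthesis and desaturation, fatty acid oxidation, lipid droplets and triglycerides, cholesterol synthesis, ferroptosis drivers, ferroptosis suppressors, the core circadian clock, the integrated stress and unfolded protein responses, hypoxia and glycolysis, antigen presentation by class I, interferon response, checkpoint ligands and cytokines, NF-kB targets, histone acetylation enzymes, lung lineage, epithelial markers, mesenchymal markers, fibroblast and endothelial markers, immune cell markers, neural and glial markers, cell cycle, and housekeeping genes. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of 1 comparison and mark, and with Fisher's exact test for gained or lost genes. Camera was repeated with an estimated correlation, and fry asked whether the genes of a list moved, on balance, one way.

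Named genes followed a fixed rule for Res against Sen and Res_shFabp7 against Res_Ctrl. It took Fabp7, and up to 4 members with the largest absolute changes past the threshold from each list that passed its test or that concerned fatty acid binding, ferroptosis or the clock; where none passed, it took members gained or lost. It took the 6 largest increases and the 6 largest decreases at gene ends past 0.05 whose groups did not overlap, an arrangement that chance gives to 10% of regions. It took the 4 gained and 4 lost genes with the most tags, and the 2 most increased and 2 most decreased regions away from gene ends. Gene models without a proper name were left out. Some genes that the rule names are not reported here. The same rule was applied afterwards to the comparisons of Res_Ctrl with Res and with Sen. Genes from lists that did not pass, and other genes outside the rule, are said to have been chosen after their values were seen.

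The alternatives were a caller threshold of 1e-10, equal numbers of peaks per library, merging within 500 bases, DESeq2 1.42.0 with its own size factors, no TMM, tags per called base as an offset, a mean of at least 50 tags, all 12 libraries of a mark in 1 fit, the replicate number as a block, gene flanks of 2.5 kb, overlap of 50% of a peak, and leaving out each library in turn. With a library left out, or at 1e-10, peaks were merged again and each gene's region was picked again. Such a gene value can belong to a different region, so a lost call need not come from the signal of 1 library. The following were chosen after seeing the data: a loess trend (span 0.3) against abundance as an offset, the median of each chromosome or of each 5 Mb window (with at least 10 regions) in each library as an offset, and the comparison of Res_Ctrl with Sen.

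The labels give the groups the same replicate numbers, and nothing in them says that a number marks a shared day or culture. Deviations of same-numbered libraries from their group means correlated above 0.1 in all 3 pairs only for H3K27ac in Res_shFabp7 and Res_Ctrl (r = 0.358, 0.128 and 0.233), so the blocked count is printed beside that result. The second knockdown library correlated better there with the third control library (r = 0.154). In the other H3K27ac comparisons the first libraries also correlated (r = 0.271 for Res and Sen, 0.363 for Res_Ctrl and Res, 0.322 for Res_Ctrl and Sen). With the replicate number as a block, 2237 H3K27ac regions rose and 1967 fell in Res against Sen. Comparisons that share libraries were set beside 10 simulations of unchanged groups and beside the overlap of independent lists.

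The tests were run on simulated counts drawn from the real libraries' means, with 100 regions changed 1.5-fold and 100 changed 2-fold. Of the 1.5-fold changes, 39% were recovered for Res against Sen in H3K27ac (12328 regions), 95% in H3K9ac (11185 regions), and, for the knockdown, 49% (16235 regions) and 93% (11152 regions). Of the 2-fold changes, 99%, 100%, 94% and 100% were recovered in the same order, with 10 false among 148 calls, 10 among 205, 11 among 154 and 5 among 198. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.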

Results

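Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, and at lysine 9 (H3K9ac), found mostly at active promoters, was profiled in mouse lung adenocarcinoma cells that were sensitive (Sen) or resistant (Res) to antibodies against the immune checkpoint receptor PD-1. Resistant cells carrying a control short hairpin RNA (Res_Ctrl) or a hairpin against Fabp7 (Res_shFabp7), which encodes a fatty acid binding protein, made up the other groups. Each mark was measured in 3 biological replicates per group. The 24 peak lists held 11771 to 28934 peaks and 2.24 to 11.5 M tags in peaks (M, 1e6). The series title concerns ferroptosis, a death caused by lipid peroxidation, and fatty acid binding proteins. The comparisons ask how the acetylated regions of resistant cells differ from those of sensitive cells, and what the loss of Fabp7 changes in resistant cells.

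Fabp7 (chromosome 10, 57784923 to 57788450, mm10), the gene targeted by the hairpin, had 0 peaks of either mark within 1 kb in all 24 libraries. A small H3K27ac peak lay 5688 bases past the end of the gene in the first Res library (57794138 to 57795921, 128 tags). A peak within 25 kb of Fabp7 was called in 3 of 3 Res libraries, 2 of 3 Res_shFabp7 libraries, and in 0 of 3 Sen and 0 of 3 Res_Ctrl libraries. H3K9ac peaks within 25 kb were called in 2 of 3 Res libraries, with 57 and 62 tags, and in 0 libraries of the other groups. A hairpin acts on the transcript, so these peaks do not check the labels of the knockdown. Of the other fatty acid binding proteins, Fabp5 alone could be tested, and only in H3K9ac, where its change between Res and Sen (0.22 ± 0.11, adjusted p = 0.12) did not pass, except under the intensity trend offset (0.29).

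Knockdown libraries held more peaks than their controls. The mean number of H3K27ac peaks was 26391 ± 2967 (SD, n = 3) in Res_shFabp7 and 21348 ± 1524 in Res_Ctrl, and of H3K9ac peaks 17485 ± 900 and 13700 ± 2280. In both marks the groups did not overlap, with an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give. Res and Sen held similar numbers of H3K27ac peaks (20657 ± 1382 and 20204 ± 3888, exact permutation p = 0.9), and Res fewer H3K9ac peaks than Sen (13347 ± 584 and 16100 ± 435, exact permutation p = 0.1). The knockdown libraries also held 1.75 times as many tags in H3K27ac peaks (7.60 ± 2.74 against 4.33 ± 0.546 M). They covered 76.3 ± 13.1 against 55.4 ± 5.37 Mb of called sequence, with 97.5 ± 19.2 against 78.1 ± 2.68 tags per called kb. For H3K9ac these values were 5.96 ± 1.18 against 3.46 ± 1.06 M tags and 45.8 ± 3.97 against 33.7 ± 7.23 Mb. The first Sen library of H3K27ac stood apart from its group, with 15856 peaks and 2.24 M tags against 23348 and 21407 peaks in the others.

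**Figure D1:**
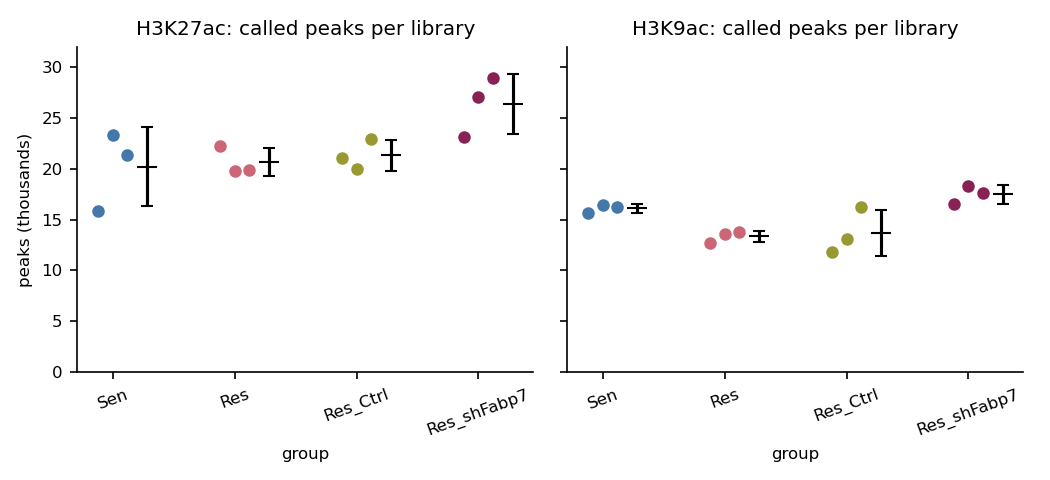
Number of deposited peaks in each library (points) with the mean and SD of 3 libraries per group, for H3K27ac and H3K9ac; the vertical axis gives peaks in units of 1000 and starts at 0. The 3 knockdown libraries lie above the 3 control libraries in both marks, and the lowest Sen library of H3K27ac holds 15856 peaks.

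Nearly all H3K9ac peaks lay on H3K27ac peaks. In libraries of the same group and number, 95.0% ± 3.9 (SD, n = 12) of H3K9ac peaks overlapped an H3K27ac peak, and 64.2% ± 8.6 of H3K27ac peaks overlapped an H3K9ac peak. By group the first share was 91.4% ± 5.47 in Sen, 95.4% ± 3.50 in Res, 95.6% ± 3.03 in Res_Ctrl and 97.8% ± 0.548 in Res_shFabp7 (n = 3 each).

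Res libraries had higher H3K27ac than Sen libraries at Trib2, a pseudokinase, and lower H3K27ac at a region shared by the zinc transporter Slc39a4 and Vps28. The region of Slc39a4 and Vps28 (chromosome 15, 76612971 to 76622442) was 7.85-fold lower in Res (-2.97 ± 0.14, adjusted p = 1.4e-05). H3K27ac fell at Gins1, part of the replicative helicase (-2.67 ± 0.20). H3K27ac also fell at the hair keratin Krt84 (-2.65 ± 0.21) and at Ggcx, the vitamin K-dependent carboxylase (-2.43 ± 0.20). Trib2 (chromosome 12, 15813710 to 15817963) was 5.00-fold higher (2.32 ± 0.16, adjusted p = 5.4e-05). It was followed by Spns2, an exporter of sphingosine 1-phosphate (2.30 ± 0.17), the zinc finger gene Zfp37 (2.29 ± 0.17), the choline transporter Slc44a1 (2.21 ± 0.17), the fatty acid transporter Slc27a1 (2.18 ± 0.23) and Ctnnal1 (2.17 ± 0.14). Of 12328 regions tested with edgeR, 2008 rose and 1800 fell, and of 8915 genes with a tested region at an end, 1320 rose and 964 fell. Per called base, the changes of Slc27a1 and Gins1 no longer passed (0.29 and -0.22). Without the second Sen library 1122 regions fell.

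H3K9ac rose most at Igf2bp1, which encodes an RNA-binding protein of fetal tissues and tumours. Its region (chromosome 11, 96000551 to 96006919) went from 42.6 ± 1.95 to 316 ± 7.07 CPM, 7.35-fold (2.88 ± 0.06, adjusted p = 8.6e-11). Sertad4 (2.54 ± 0.12), the ETS factor Etv1 (2.33 ± 0.10), the GATA-type repressor Trps1 (2.25 ± 0.13), Zfp37 (2.19 ± 0.08) and the transcription factor Maf (2.11 ± 0.12) followed. The largest decreases were at a region shared by Them6 and Psca (chromosome 15, 74711223 to 74723387; -2.58 ± 0.11) and at the collagen receptor subunit Itga2 (-2.41 ± 0.08). Next came the adaptor Grb7 (-2.21 ± 0.11), Fjx1 (-1.97 ± 0.10) and lactate dehydrogenase A, Ldha (-1.89 ± 0.11, adjusted p = 1.8e-07). In all, 3145 of 11185 regions rose and 2948 fell, and 2712 and 2482 of 9788 genes. The decrease at Them6 and Psca was not seen per called base (0.02). It was -1.54 without the second Sen library, and that at Them6 was -0.81 without the third.

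Genes of the integrated stress and unfolded protein responses, which are induced by amino acid shortage and by misfolded proteins, passed camera as higher in Res. In H3K27ac 9 of 18 tested members rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 7.6e-05), and in H3K9ac 13 of 22 rose and 3 fell (2.8e-06). These calls were lost with an estimated correlation (adjusted p = 0.849 and 0.474 with an estimated correlation; lowest of any alternative 3.0e-09 and 1.6e-13). The pseudokinase Trib3 rose by 1.69 ± 0.21 in H3K27ac and 1.51 ± 0.12 in H3K9ac, Chac1, which degrades glutathione, by 1.54 ± 0.15 and 1.45 ± 0.08, and the transcription factor Xbp1 by 1.01 ± 0.11 and 1.02 ± 0.05. Herpud1, of protein degradation at the endoplasmic reticulum, rose in H3K27ac (1.04 ± 0.12), and asparagine synthetase, Asns, in H3K9ac (1.08 ± 0.10). Epithelial markers passed as lower: 5 of 11 fell and 1 rose in H3K27ac (6 and 2 adjusted over the list alone; adjusted p = 0.049), and 7 of 12 fell and 1 rose in H3K9ac (0.0018). With an estimated correlation they did not pass (adjusted p = 0.849 and 0.35 with an estimated correlation; lowest of any alternative 0.0033 and 4.6e-07). The keratins Krt7 (chromosome 15, 101410062 to 101416350) and Krt18 fell in H3K27ac (-1.43 ± 0.19 and -1.09 ± 0.07) and in H3K9ac (-1.44 ± 0.07 and -0.98 ± 0.07). The junction gene Tjp3 fell in H3K27ac (-0.82 ± 0.14) and the desmosomal genes Pkp3 and Dsp in H3K9ac (-0.79 ± 0.12 and -0.64 ± 0.08). The tight junction gene Marveld3 rose in H3K27ac (1.08 ± 0.16; 0.11 per called base and 0.091 with regions within 2500 bases of a gene, both below the threshold). Cholesterol synthesis genes passed as lower in H3K9ac: 13 of 20 fell and 2 rose (adjusted p = 0.012). This call too was lost (adjusted p = 0.598 with an estimated correlation; lowest of any alternative 0.0049). The sterol carrier Stard4 was at -0.97 ± 0.08 (-0.083 per called base, below the threshold), Idi1 at -0.70 ± 0.12 and Msmo1 at 0.66 ± 0.11. In H3K27ac 6 of 16 fell and 0 rose (7 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.211). Between Res_Ctrl, also labelled resistant, and Sen, camera called 0 lists in either mark. The list calls of Res against Sen therefore hold for the Res libraries and not for resistant cells at large.

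The H3K27ac call for epithelial markers was also lost without the first or second Res library (adjusted p = 0.072 and 0.067) and without the second or the third Sen library (0.13 and 0.27), over a range of 0.0033 to 0.85 for all alternatives. Per called base, epithelial markers and cholesterol synthesis no longer passed in H3K9ac (0.078 each; ranges 4.6e-07 to 0.35 and 0.0049 to 0.60).

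Ferroptosis genes moved both ways. Among suppressors, Gch1, which makes the antioxidant cofactor tetrahydrobiopterin, rose in H3K27ac (1.34 ± 0.21) and H3K9ac (1.46 ± 0.13). The autophagy adaptor Sqstm1 rose too (0.92 ± 0.14 and 0.67 ± 0.08), and Mboat1, which remodels phospholipids, fell (-0.59 ± 0.12 and -0.60 ± 0.07; in H3K27ac -0.17 per called base, below the threshold). Heme oxygenase, Hmox1, rose in H3K9ac (1.23 ± 0.17) and had gained its H3K27ac peak. Acsl3, an acyl-CoA synthetase that shares its region with Utp14b, rose in H3K27ac (0.51 ± 0.14), a call lost without the first or second Res library (0.49 and 0.43) or the second or the third Sen library (0.49 and 0.47). It was also lost per called base (0.056) and after removing chromosome medians (0.36). In total 4 of 19 suppressors rose and 5 fell in H3K27ac (camera adjusted p = 0.845), and 7 of 21 rose and 8 fell in H3K9ac (0.969). Among drivers, besides Chac1, the glutamine transporter Slc1a5 rose (0.80 ± 0.12 and 0.80 ± 0.07) and so did Cyb5r1 (0.77 ± 0.20 and 0.83 ± 0.10), though in H3K27ac not without the second Sen library (0.72), after removing chromosome medians (0.61) or with regions within 2500 bases of a gene (0.11). The transferrin receptor Tfrc fell in H3K27ac (-0.80 ± 0.20) and Lpcat3, which puts polyunsaturated fatty acids into phospholipids, in H3K9ac (-0.71 ± 0.08). Drivers counted 4 higher and 2 lower of 18 in H3K27ac (5 and 3 adjusted over the list alone; adjusted p = 0.504) and 7 and 6 of 21 in H3K9ac (0.405). Chosen after their values were seen, Gpx4, the peroxidase that detoxifies lipid peroxides, fell by 0.32 ± 0.09 and 0.28 ± 0.06, and Acsl4, which activates polyunsaturated fatty acids, fell in H3K9ac (-0.43 ± 0.17).

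Clock genes did not move as a list (2 of 16 rose and 0 fell in H3K27ac, adjusted p = 0.889; 3 of 17 rose and 4 fell in H3K9ac, 0.726). Per1, of the negative limb of the clock, rose in H3K27ac (1.03 ± 0.17; 0.19 per called base, below the threshold), and the repressor Nfil3 in both marks (0.97 ± 0.18 and 0.49 ± 0.10). In H3K9ac the nuclear receptor Rorb rose (1.11 ± 0.12), and the activator Dbp, whose region is shared with Car11, fell (-0.73 ± 0.12). Cry2 also fell (-0.36 ± 0.12), a call lost without the second Res library (-0.19) or the second or the third Sen library (-0.34 and -0.33). It was also lost per called base (-0.044) and after removing the medians of chromosomes (-0.20) or 5 Mb windows (-0.23). Among histone acetylation enzymes, 5 of those with a peak lost it in H3K9ac (Fisher's exact test, adjusted p = 0.0231): Acss2, which makes acetyl-CoA from acetate, the reader Brd3, and the deacetylases Hdac11, Hdac6 and Hdac8. At a caller threshold of 1e-10 Hdac11, Hdac6 and Hdac8 no longer counted as lost, and with equal numbers of peaks per library Brd3 alone of the 5 did. The p was not computed again in these settings, and Res held fewer H3K9ac peaks than Sen. By tags, 11 of 24 rose and 6 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.726). Hdac5 (0.56 ± 0.10) and Brd2 (shared with H2-DMa; 0.41 ± 0.08) were higher, and Kat8 (-0.44 ± 0.12) and Sirt2 (shared with Nfkbib; -0.58 ± 0.19) lower. These 4 calls were lost after removing the median of each chromosome, which left 0.22, 0.12, -0.25 and -0.39, or of 5 Mb windows (0.21, 0.15, -0.22 and -0.35), and that of Sirt2 also without the second or the third Sen library (-0.57 and -0.56). Without the second Res library Sirt2 was at -0.33. In H3K27ac 4 of 22 enzymes rose and 3 fell (0.845).

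No other list passed in Res against Sen. Lung lineage genes counted 3 higher and 5 lower of 15 in H3K27ac (adjusted p = 0.683) and 4 and 6 of 14 in H3K9ac (0.156). Chosen after their values were seen, the lung and gut endoderm factors Foxa2 (-0.94 ± 0.08 and -1.07 ± 0.06), Hnf4a (-1.08 ± 0.17 and -0.98 ± 0.13) and Gata6 (-0.57 ± 0.10 and -0.76 ± 0.06) fell in both marks. Without the second Sen library Foxa2 was at -0.45 in H3K27ac. Sox9, of the distal lung bud, rose in both (2.03 ± 0.32 and 1.02 ± 0.10). Likewise chosen, the lipid droplet coat gene Plin2 (chromosome 4, 86667331 to 86678559) rose 2.84-fold in H3K27ac (1.51 ± 0.11) and 3.80-fold in H3K9ac (1.92 ± 0.15). Its list had 3 higher and 1 lower of 17 (2 and 1 adjusted over the list alone; 0.845), and 5 higher and 3 lower of 17 (0.969). The matrix genes Fn1 (1.17 ± 0.15 and 1.15 ± 0.07) and Sparc (1.20 ± 0.09 and 1.26 ± 0.07), chosen the same way, rose, Sparc in H3K27ac not past the threshold per called base (0.20). Mesenchymal markers counted 2 higher and 3 lower of 11 (0.504) and 4 and 4 of 12 (0.435). At the interferon-induced Isg15, which shares its region with Agrn, both marks fell (-2.28 ± 0.11 and -1.73 ± 0.07). Its H3K9ac value was chosen after it was seen. The interferon list had 1 higher and 2 lower of 11 (0.504) and 6 and 4 of 16 (7 and 4 adjusted over the list alone; 0.726). Hypoxia and glycolysis genes had 3 higher and 7 lower of 21 (4 and 8 adjusted over the list alone; 0.504) and 6 and 14 of 22 (0.181). Class I antigen presentation had 1 higher and 0 lower of 10 (0.615) and 4 and 1 of 12 (0.596). The heavy chain H2-K1, chosen after its value was seen, was higher in H3K9ac (1.03 ± 0.18).

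The remaining lists are given as higher and lower of those tested, in H3K27ac and then in H3K9ac. Checkpoint ligands and cytokines had 4 and 1 of 13 and 5 and 2 of 15 (adjusted p = 0.683 and 0.296), and NF-kB targets 3 and 4 of 15 and 5 and 3 of 14 (0.504 and 0.726). Cell cycle genes had 2 and 6 of 24 and 5 and 12 of 27 (0.504 and 0.726), and housekeeping genes 5 and 4 of 18 and 6 and 8 of 18 (0.845 and 0.726). Fatty acid oxidation had 0 and 1 of 12, which was Cpt1a, and 5 and 3 of 16 (0.926 and 0.726). Fatty acid synthesis and desaturation had 3 and 2 of 14 and 6 and 6 of 16 (0.533 and 0.726). Fatty acid uptake had 1 and 1 of 12, which were Slc27a1 and Pparg, and 4 and 3 of 12 (0.648 and 0.726). Adjusted over the list alone, the counts of these lists in H3K27ac were 4 and 2, 4 and 7, 4 and 7, 5 and 5, 0 and 1, 3 and 3, and 1 and 1. In H3K9ac housekeeping genes had 6 and 10 and fatty acid uptake 4 and 4 adjusted over the list alone. The camera direction was opposite in sign to the median for checkpoint ligands and lipid droplets (up, median below 0) and the interferon response (down, median above 0) in both marks. In H3K27ac this also held for the clock (up, median -0.13), fatty acid oxidation and lung lineage, and in H3K9ac for fatty acid synthesis and immune cell markers. Of markers of other cell types, immune cells had 1 (Cd68) and 1 (Cd14) of 3 and then 0 and 1 (Cd14) of 4, and neural and glial markers 0 and 2 of 2 in each mark, which were Nes and Mbp. Of fibroblast and endothelial markers 2 could be tested in H3K27ac, where Rgs5 rose, and 0 in H3K9ac.

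Peaks present in only 1 of both cell states were many. In H3K27ac 1642 regions were called in 3 of 3 Res and 0 of 3 Sen libraries, and 941 in the reverse; in H3K9ac 408 were gained and 2188 lost. The Sen libraries of H3K9ac held more tags in peaks than those of Res (8.65 ± 3.91 against 3.51 ± 0.446 M) over 44.1 ± 5.60 against 31.3 ± 2.21 Mb. Gained and lost H3K9ac regions were about as weak, with a median percentile by tags of 22.3 and 21.6 within their own libraries, against 32.8 and 46.8 in H3K27ac. The gained genes with the most H3K27ac tags were Wnt10b (913 ± 229 tags, n = 3; chromosome 15, 98771079 to 98777190), a Wnt ligand, Mxra8 (799 ± 106), Vxn (646 ± 68.1) and the LIM homeobox gene Lhx9 (628 ± 241). Lhx9 did not count as gained at a caller threshold of 1e-10 or with equal numbers of peaks. The lost ones were Csf1, which encodes the macrophage growth factor M-CSF (1650 ± 630 tags in Sen; chromosome 3, 107731185 to 107745476), Myrf (1312 ± 433), Bicc1 (760 ± 252) and Serpind1 (615 ± 241). At Csf1 the marks parted: all 3 Res libraries had H3K9ac peaks there, with 835 ± 21.0 tags at 107736148 to 107745357. H3K9ac near the other end of the gene was higher in Res than in Sen (0.86 ± 0.07, adjusted p = 1.1e-06). Whether this region was masked, or the input high, in the H3K27ac lists of Res is not given in the sources used here, so the absence of H3K27ac from Csf1 is uncertain. With merging within 500 bases Csf1 did not count as lost. In H3K9ac the gained genes were Gli3 (519 ± 38.5), an effector of Hedgehog signalling, the collagen receptor Ddr2 (476 ± 78.0), Stc2 (471 ± 34.6) and Adgrl2 (443 ± 54.4). The lost ones were Bicc1 (1396 ± 704), Gcnt3 (1056 ± 448), Eps8l3 (937 ± 482) and Arhgap40 (897 ± 418). Cdkn2a and Cdkn2b, inhibitors of the cell cycle, lost their H3K9ac peaks too, in the chromosome 4 segment described further on. With equal numbers of peaks per library the counts were 1472 gained and 1254 lost in H3K27ac and 739 and 930 in H3K9ac; without the first Sen library 2955 H3K27ac regions were lost.

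**Figure D2:**
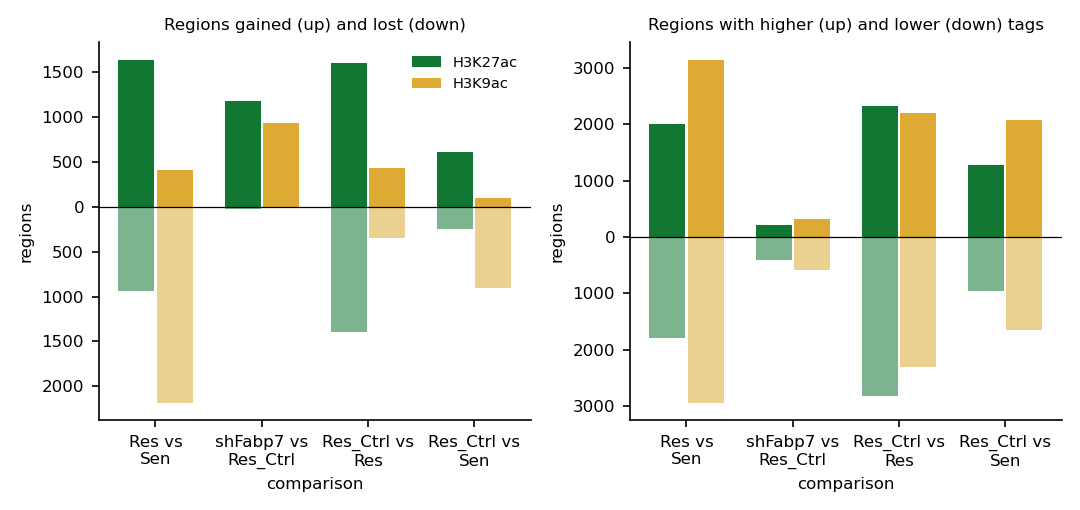
Numbers of regions gained or lost (a peak in 3 of 3 libraries of one group and 0 of 3 of the other) and with higher or lower tag counts (edgeR, adjusted p of 0.05), per comparison and mark; bars above 0 are gained or higher, bars below 0 lost or lower. Knockdown gained 1184 and lost 28 H3K27ac regions, while its tag counts rose in 215 regions and fell in 411.

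Away from gene ends, H3K27ac rose most inside Galk2 (chromosome 2, 125917540 to 125944964; 3.58 ± 0.42) and 11137 bases from Nsmaf (chromosome 4, 6465977 to 6475886; 3.14 ± 0.15). It fell most inside Tspan15 (chromosome 10, 62217974 to 62225316; -3.19 ± 0.21) and 117073 bases from Kdm8 (chromosome 7, 125320387 to 125327547; -3.08 ± 0.20). H3K9ac rose most inside Nfia (chromosome 4, 97750917 to 97753441; 2.78 ± 0.11) and 196996 bases from Klf4 (chromosome 4, 55729471 to 55736016; 2.58 ± 0.21). It fell most 12597 bases from Cdk18 (chromosome 1, 132094593 to 132100950; -2.10 ± 0.08) and inside Rap1gap (chromosome 4, 137704379 to 137708575; -2.04 ± 0.12).

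Changes also followed whole chromosomes. Between Res and Sen the median change of regions on chromosome 11 was 0.39 in H3K27ac and 0.35 in H3K9ac. On chromosome 17 it was 0.32 and 0.29, on chromosome 8 it was 0.32 and 0.31, and on chromosome 6 it was -0.35 and -0.31. Igf2bp1 and Spns2 lie on chromosome 11 and Slc27a1 on chromosome 8. After removing the median of each chromosome in each library, 1327 H3K27ac regions rose and 1335 fell, and 1973 and 1978 H3K9ac regions. After removing the medians of 5 Mb windows, 1146 and 1208, and 1807 and 1732 did.

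**Figure D3:**
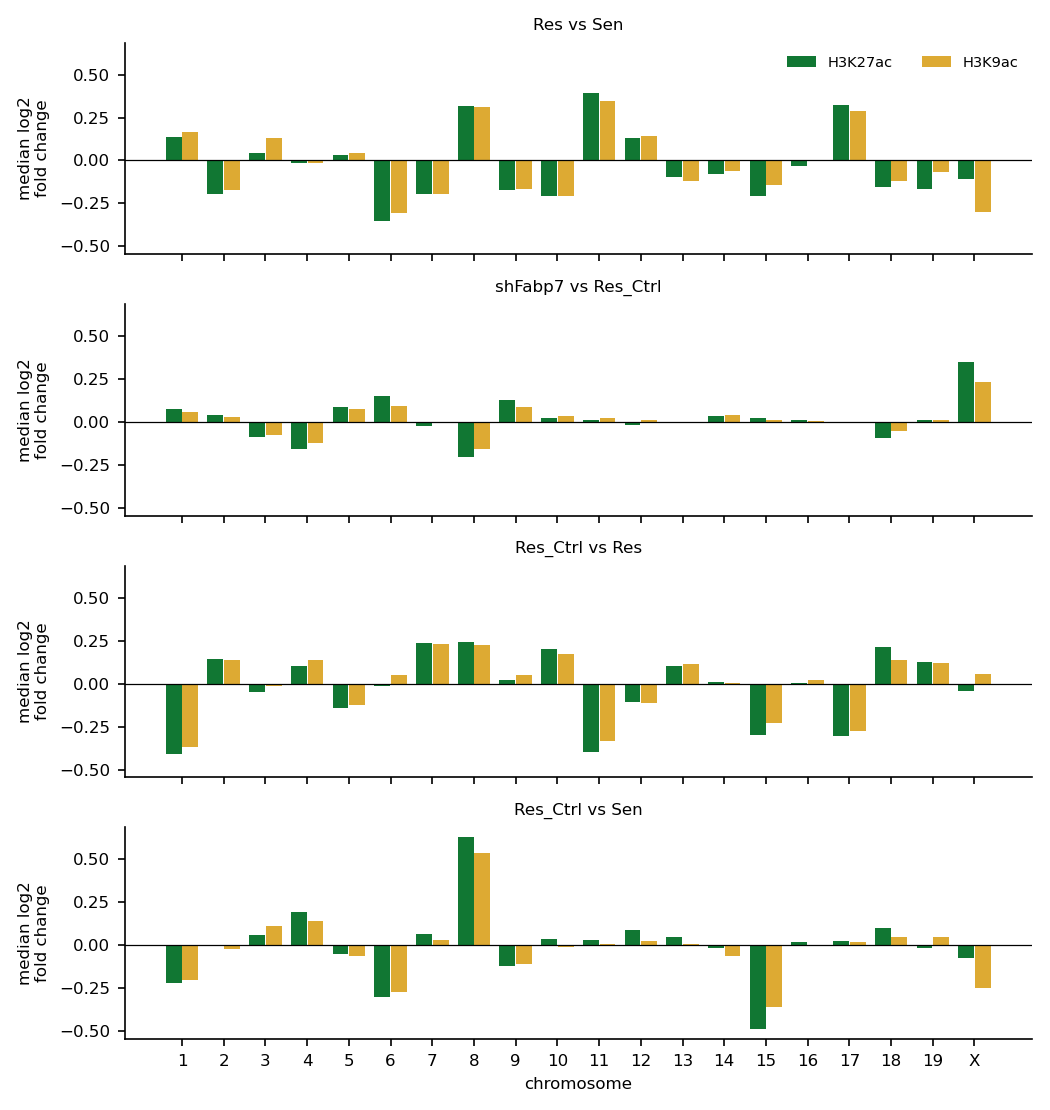
Median log2 change of the tested regions of each chromosome in H3K27ac and H3K9ac, per comparison. Both marks move together, for example at 0.39 and 0.35 on chromosome 11 in Res against Sen, and at 0.35 and 0.24 on chromosome X after knockdown.

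One segment of chromosome 4 had no peak in any Res library. From 87982415 to 89525790 (1.54 Mb) the Res libraries had 0 peaks of either mark. Res_Ctrl libraries had 24 to 26 H3K27ac and 19 to 26 H3K9ac peaks, Res_shFabp7 libraries 29 to 31 and 20 to 22, and Sen libraries 10 to 29 and 18 to 19. The segment holds Mtap, of methionine salvage, Cdkn2a and Cdkn2b, part of the type I interferon cluster with Ifnb1, and Focad. It was the longest run of H3K27ac regions missing in Res among those called in at least 7 of the 9 other libraries. It held 14 regions in a row against at most 7 in 1000 shuffles, and H3K9ac gave a run of 13 against at most 7. Runs longer than in the shuffles were also found in H3K27ac for Sen, with 8 against at most 5 (chromosome 4, 100775686 to 102571689), and for Res_shFabp7, with 3 against at most 2.

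**Figure D4:**
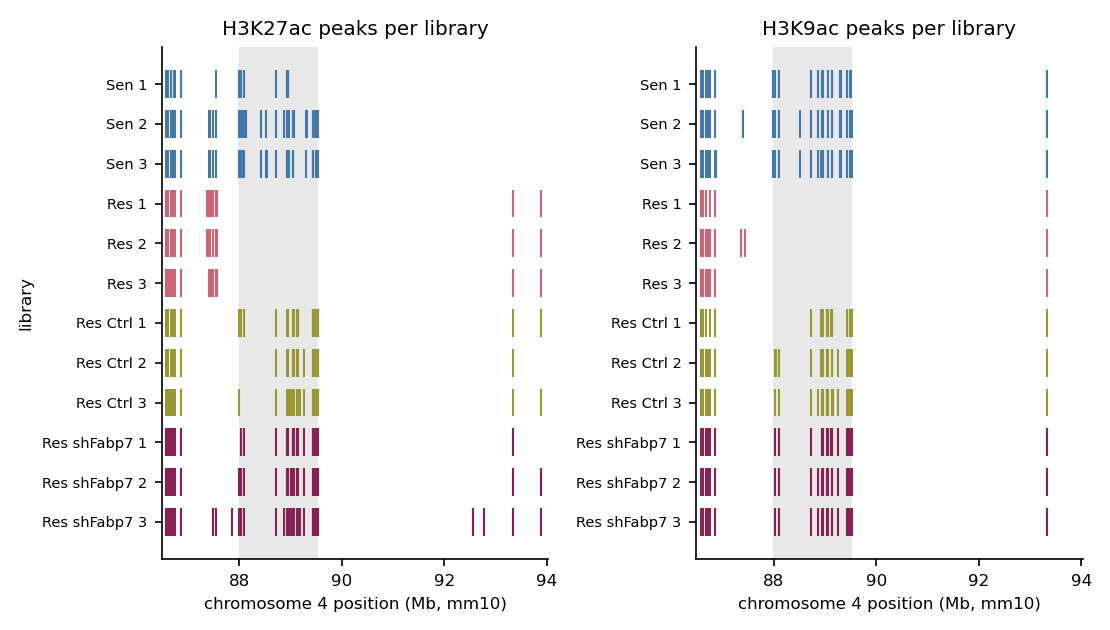
Deposited peaks of each library along the segment of chromosome 4 between 87982415 and 89525790 (mm10) (grey) and its flanks; each line is a library and each tick a peak. The 3 Res libraries of each mark have 0 peaks in the segment, and Res_Ctrl libraries 19 or more.

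H3K27ac differed in both directions between Res_shFabp7 and Res_Ctrl. Changes after knockdown, here and below, are differences between these groups. Expression of Fabp7 was not measured here, so an effect of its loss cannot be told apart from other differences between these cells. H3K27ac rose most at Efnb1, which encodes the ligand ephrin-B1 (chromosome X, 99134880 to 99140857; 1.45 ± 0.19, 2.73-fold, adjusted p = 0.0039) and the VEGF receptor Flt1 (1.33 ± 0.18). Then came the granzyme Gzme (1.23 ± 0.20), Pin4 (1.07 ± 0.23), Phyh, of peroxisomal fatty acid oxidation (1.05 ± 0.20), and Arhgef5 (1.05 ± 0.15). It fell most at Ddah1, which degrades methylated arginines (chromosome 3, 145758092 to 145759725; -1.24 ± 0.24, 2.37-fold lower, adjusted p = 0.018) and Megf6 (-1.22 ± 0.19). Then came the receptor Notch1 (-1.21 ± 0.24), the metallothionein Mt2 (-1.20 ± 0.19), Ptgr1 (-1.15 ± 0.18) and Klk9 (-1.14 ± 0.23). Of 16235 regions 215 rose and 411 fell, and of 9610 genes 72 rose and 112 fell. With the replicate number as a block, 502 regions rose and 939 fell. The counts fell to 41 higher and 127 lower without the second knockdown library, 42 and 122 without the third, and 121 and 126 without the second control library. They were 165 and 247 without the first knockdown library and 184 and 174 without the third control library, so that decreases did not outnumber increases in every fit. DESeq2 gave 376 and 574, tags per called base 396 and 916, a caller threshold of 1e-10 166 and 258, and all 12 libraries in the fit 51 and 119.

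Many of these gene calls were lost per called base or with 1 library left out, where regions were merged and picked again. Per called base none of the 6 increases passed: Efnb1 was at -0.02, Flt1 -0.15, Phyh -0.08, Gzme 0.03, Pin4 0.03 and Arhgef5 0.04. Without the second knockdown library Flt1 was at 0.46, Phyh 1.06, Ddah1 -1.16, Notch1 -1.13 and Klk9 -1.24, none of them past the threshold. The same held without the third knockdown library for Gzme (1.15), Ddah1 (-1.09) and Notch1 (-1.09), without the second control library for Phyh (0.97), and without the third for Notch1 (-1.07) and Klk9 (-1.08). Pin4 passed only in the fit without the first control library; the others gave 0.91 to 1.14. It was also lost after removing the medians of chromosomes (0.74) or 5 Mb windows (0.57), and Ddah1 after removing those of windows (-1.02). Megf6, Mt2 and Ptgr1 passed in every fit with a library left out.

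H3K9ac fell most after knockdown at Serpinh1, a chaperone of collagen (chromosome 7, 99350841 to 99353529), from 61.4 ± 2.05 to 17.0 ± 6.79 CPM, 3.53-fold lower (-1.82 ± 0.20, adjusted p = 2.7e-04). Adgra2 (-1.29 ± 0.16), Ddah1 (-1.26 ± 0.12), the homeobox gene Dlx4 (-1.08 ± 0.17), the proteoglycan Bcan (2.01-fold lower) and Sipa1l2 (-0.99 ± 0.11) followed. The largest increases were at Hip1r, an endocytic adaptor (1.34 ± 0.10, adjusted p = 3.8e-05) and the developmental factor Eya1 (1.17 ± 0.24). They were followed by Cfap410 (1.08 ± 0.17), Pde6c (0.93 ± 0.14), Lax1 (0.83 ± 0.19) and the nuclear pore gene Nup210 (0.82 ± 0.19). Of 11152 regions 317 rose and 578 fell, and of 9622 genes 214 and 344. Without the second knockdown library Hip1r was at 0.04 and Cfap410 at 0.30. Per called base they were at -0.45 and -0.08, and the fall of Hip1r passed the threshold (edgeR adjusted p = 9.4e-04). The calls of Eya1 and Lax1 were lost without any 1 of the knockdown libraries (1.15 to 1.18 and 0.77 to 0.89), and that of Lax1 also without the second control library (0.65); without the third, Lax1 was at 1.26. That of Nup210 was lost without any knockdown library (0.22 without the third) or the second control library (0.78). With DESeq2 the calls of Eya1 (1.18), Lax1 (0.87) and Nup210 (0.87) were lost, and per called base those of Lax1 (0.13) and Nup210 (0.083). Nup210 was also lost at a caller threshold of 1e-10 (0.21), after removing window medians (0.72) and with all 12 libraries in the fit (0.20). Regions that rose and fell numbered 94 and 266 without the first knockdown library, 79 and 303 without the second, 98 and 224 without the third, and 160 and 345 without the second control library; 509 rose without the third.

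Checkpoint ligands and cytokines passed camera as lower after knockdown, though few members did: 1 of 17 fell in H3K27ac (4 adjusted over the list alone; camera adjusted p = 0.0064), and 4 of 15 in H3K9ac (5, and 1 higher, adjusted over the list alone; 0.0057). The list passed neither with an estimated correlation (adjusted p = 0.347 and 0.423 with an estimated correlation; lowest of any alternative 0.00062 and 0.00021) nor by fry (0.069 and 0.10). Csf1 fell by 0.50 ± 0.07 in each mark, the neutrophil chemokine Cxcl5 by 0.64 ± 0.11, the chemokine Cx3cl1 by 0.53 ± 0.12 and Vegfa by 0.18 ± 0.05 in H3K9ac. In H3K9ac 3 of 16 interferon response genes fell (5 adjusted over the list alone; adjusted p = 0.024), a call that was lost (adjusted p = 0.423 with an estimated correlation; lowest of any alternative 0.0089). These were the antiviral Bst2 (-0.54 ± 0.15), the kinase Jak1 (-0.39 ± 0.10) and the inhibitor Socs1, whose region is shared with Tnp2 (-0.29 ± 0.06). Neural and glial markers passed as lower in H3K27ac (2 of 3, adjusted p = 1.3e-05), but not with an estimated correlation (adjusted p = 0.159 with an estimated correlation; lowest of any alternative 5.1e-08). This came through the intermediate filament gene Nes, shared with Bcan (-0.86 ± 0.10), and S100b, shared with Dip2a (-0.64 ± 0.14). Epithelial markers passed as lower (adjusted p = 0.026) and housekeeping genes as higher (0.039) in H3K27ac, with 0 of 11 and 0 of 18 members past the edgeR threshold, and medians of -0.12 and 0.12. Both calls were lost (adjusted p = 0.426 and 0.918 with an estimated correlation; lowest of any alternative 0.00013 and 0.014).

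List calls after knockdown were also lost without 1 library: for checkpoint ligands in H3K27ac without the first knockdown or second control library (adjusted p = 0.089 and 0.082), and in H3K9ac without the third control library (0.086). The interferon response lost it without the third knockdown or the first or the third control library (0.096, 0.061 and 0.086). For epithelial markers this held without the first knockdown and the second and the third control libraries (0.19, 0.41 and 0.068), and for housekeeping genes without the first and the third knockdown and second control libraries (0.089, 0.10 and 0.19). After removing chromosome or window medians the interferon response (0.077 and 0.19) and housekeeping genes (0.70 and 0.65) did not pass, nor epithelial markers after removing window medians (0.074) or the intensity trend (0.13). Per called base epithelial markers (0.24) and checkpoint ligands in H3K9ac (0.069) did not pass. By fry the interferon response (0.051), epithelial markers (0.25) and housekeeping genes (0.35) did not either. Cx3cl1 was lost without the first or the third knockdown library (-0.45 and -0.49) or the second control library (-0.48). Chromosome and window medians, once removed, ended the calls of Cx3cl1 (-0.36 and -0.31), Bst2 (-0.38 and -0.36) and Jak1 (-0.26 and -0.21). Cx3cl1 was lost as well per called base (-0.14) and with regions within 2500 bases of a gene (-0.22), and Bst2 under the intensity trend offset (-0.51). Per called base Csf1 in H3K9ac (-0.067), Vegfa (0.025) and Socs1 (-0.16) did not pass. With all 12 libraries in the fit Socs1 (-0.30) and Nes (-0.87) did not. Window medians ended the calls of Vegfa (-0.19) and S100b (-0.64), and the intensity trend offset that of Vegfa (-0.16). Vegfa was lost in every such fit except that without the second control library (-0.20 to -0.16), and Bst2 in all but that without the first control library (-0.66 to -0.44). Jak1 was lost without any 1 knockdown library (-0.40 to -0.37) or the first control library (-0.31), and S100b in all but that without the first control library (-0.73 to -0.50).

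Ferroptosis genes seldom passed after knockdown. Among suppressors Acsl3 rose in both marks (0.49 ± 0.11 and 0.22 ± 0.06; -0.06 and -0.02 per called base) and Sqstm1 in H3K9ac (0.50 ± 0.07; -0.15 per called base). Of 22 suppressors tested in each mark 0 fell by edgeR (3 higher in H3K9ac adjusted over the list alone; camera adjusted p = 0.739 and 0.691). The Acsl3 call was kept without the first control library in H3K27ac (others 0.44 to 0.55) and without the third in H3K9ac (others 0.21 to 0.23), and lost in every other fit with a library left out. It was lost after removing chromosome or window medians (0.43 and 0.44; 0.17 and 0.17) and with all 12 libraries (0.48 and 0.21), and in H3K9ac with DESeq2 and the replicate block (0.22 each). Of drivers 0 of 18 passed in H3K27ac (0.864), and of 19 in H3K9ac only the lipoxygenase gene Aloxe3, shared with Hes7, fell (-0.38 ± 0.08; -0.35 without the third knockdown library, below the threshold; 0.871). Clock genes had 0 of 16 past the threshold in each mark (3 higher and 1 lower in H3K27ac adjusted over the list alone; 0.739 and 0.131). Rorb gained a peak in both marks (92.7 ± 8.96 and 125 ± 33.0 tags, n = 3), which did not count as gained with equal numbers of peaks in either mark, nor at a caller threshold of 1e-10 in H3K27ac. Fabp5 was at -0.53 ± 0.17 in H3K9ac (adjusted p = 0.076), which did not pass over all genes and did adjusted over the list alone, per called base (-0.33) and with all 12 libraries in the fit (-0.53).

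In the remaining lists few members passed after knockdown, and these were chosen after their values were seen. The lipase gene Pnpla2, of lipid droplet breakdown, fell in H3K27ac (-0.85 ± 0.12; 1 of 17 lipid droplet genes, adjusted p = 0.322), and Gpat4 in H3K9ac (-0.21; 1 of 16, 0.283). Of class I genes 0 of 10 passed in H3K27ac (0.624) and 2 of 11 fell in H3K9ac (0.065), H2-K1 (-0.70 ± 0.12) and H2-D1 (-0.38 ± 0.09, lost without any 1 knockdown library or the second control library, -0.40 to -0.35). Of mesenchymal markers Sparc rose (0.71 ± 0.14) and Snai1 fell (-0.47 ± 0.11) in H3K27ac (13 tested, 0.739), and Snai1 (-0.69) and Axl (-0.20) fell in H3K9ac (11 tested, 0.205). In H3K27ac among fits with a library left out the call of Snai1 was kept only without the first control library (others -0.51 to -0.42) and that of Sparc only without the first or second control library (others 0.65 to 0.76). Per called base both were lost (-0.15 and 0.074), and Snai1 also at a caller threshold of 1e-10 (-0.45) and after removing window medians (-0.44). Of hypoxia genes 1 of 22 fell in H3K27ac (0.072), and in H3K9ac Car9 (-0.62), Egln3 (-0.51) and Vegfa fell and Tpi1 (0.34) and Pgk1 (0.31) rose (21 tested, 0.414). Of lung lineage genes 0 of 14 passed in H3K27ac (0.739), while Sox9 fell (-0.55) and Hmga2 rose (0.25) in H3K9ac (13 tested, 0.761). Epithelial markers in H3K9ac had Dsp higher (0.25) and Krt7 lower (-0.38 ± 0.06; 12 tested, 0.065), neural markers Nes lower (-0.58 ± 0.07; -0.055 per called base, below the threshold), and NF-kB targets Relb higher (0.42) and Tnfaip3 lower (-0.30; 13 tested, 0.691).

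Of NF-kB targets in H3K27ac (16 tested, adjusted p = 0.739), Vcam1 rose by 0.57 ± 0.13. It was at -0.10 without the second knockdown library. Per called base it was at -0.35, a fall past the threshold (edgeR adjusted p = 0.012). Of the fits with a library left out it passed only in that without the first control library. With all 12 libraries it did not pass (0.56). Tnfaip3 fell by 0.36 ± 0.09, a call lost in all 6 fits with a library left out (-0.43 to -0.30). It was lost too per called base (-0.074), without TMM (-0.34), at a caller threshold of 1e-10 (-0.34) and with all 12 libraries (-0.37). Under the intensity trend, chromosome and window offsets it was lost as well (-0.30, -0.39 and -0.24). In H3K9ac single genes fell in fatty acid oxidation (Ppargc1a, -0.78; 0.414), fatty acid uptake (Acsl1, -0.40; 0.591), the cell cycle (Mki67, -0.28; 0.691) and the stress list (Herpud1, -0.28; 0.871). Sirt7 rose among acetylation enzymes (0.34; 0.715), and 2 of 18 housekeeping genes rose (0.065). In H3K27ac edgeR called 0 genes in these fatty acid lists, the cell cycle, the stress list and acetylation enzymes (each 0.739), and in fatty acid synthesis (0.739, and 0 in H3K9ac, 0.628), cholesterol synthesis (0.739, and 0 in H3K9ac, 0.691). The same held for the interferon response (0.238) and immune cell markers (0.739, and 0 in H3K9ac, 0.591). Fibroblast and endothelial markers had 0 of 2 called in H3K27ac. Adjusted over the list alone, counts differed in H3K27ac for hypoxia (0 higher and 2 lower) and lipid droplets (1 and 2). In H3K9ac they differed for epithelial markers (1 and 5), fatty acid oxidation (0 and 0), fatty acid uptake (1 and 2), acetylation enzymes (0 and 0), hypoxia (2 and 5), the stress list (1 and 2), lung lineage (2 and 3), neural markers (0 and 2) and immune cell markers (0 and 1).

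Far more regions were gained than lost in Res_shFabp7 against Res_Ctrl: 1184 against 28 in H3K27ac and 937 against 5 in H3K9ac. The gained genes with the most H3K27ac tags were the interleukin receptor chain Il2rb (258 ± 132 tags, n = 3), the interferon-induced Ifit3b (255 ± 89.7), Tnni3k (250 ± 66.8) and Fam83f (198 ± 94.4). The lost ones were the Wnt ligand Wnt5a (126 ± 84.7), Psrc1 (108 ± 59.3), Bmp7 (90 ± 37.5) and Cpne5 (74.3 ± 30.1). None of these 4 losses was kept at a caller threshold of 1e-10, nor that of Wnt5a without the first control library. In H3K9ac a region shared by Eif4enif1 and Sfi1 (chromosome 11, 3200905 to 3204567; 801 ± 177), Clic6 (386 ± 106) and the stem cell factor Sox2 (342 ± 60.3) were gained, and Sprr1a (133 ± 26.6) and Ampd3 (80.7 ± 18.5) were lost. Neither loss was kept at a caller threshold of 1e-10 or with equal numbers of peaks, and the gain at Eif4enif1 and Sfi1 was not kept with equal numbers. With equal numbers of peaks per library, which in part forces a balance, 427 regions were gained and 221 lost in H3K27ac and 194 and 129 in H3K9ac. Without the first knockdown library 3495 H3K27ac and 1581 H3K9ac regions were gained, and without the third control library 2043 and 2884. H3K27ac losses were 64 without the third knockdown, 51 without the first control and 74 without the second control library, and H3K9ac losses 25 without the first control library.

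Away from gene ends, H3K27ac rose most after knockdown inside Itgb3 (chromosome 11, 104637816 to 104642465; 1.68 ± 0.26; -0.02 per called base) and Stard13 (chromosome 5, 151373358 to 151378222; 1.67 ± 0.21). It fell most inside Camta1 (chromosome 4, 151471247 to 151475251; -2.29 ± 0.18) and 181621 bases from Zfp703 (chromosome 8, 26793065 to 26795715; -1.47 ± 0.18). H3K9ac rose most inside Myo5c (chromosome 9, 75235555 to 75239917; 1.44 ± 0.12) and 1145 bases from Arhgef5 (chromosome 6, 43290465 to 43294272; 1.25 ± 0.13; 0.19 per called base). It fell most inside Mmp24 (chromosome 2, 155808830 to 155811753; -1.25 ± 0.11) and Serinc2 (chromosome 4, 130273330 to 130275782; -1.17 ± 0.16). Chromosome X, with Efnb1 and Pin4, had a median of 0.35 in H3K27ac and 0.24 in H3K9ac, and chromosome 8, with Mt2, Adgra2, Cx3cl1 and Bst2, of -0.21 and -0.15. After removing chromosome medians 153 H3K27ac regions rose and 235 fell, and 163 and 365 H3K9ac regions.

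Regions called in both comparisons moved the opposite way more often than independent lists would. In H3K27ac this lean was lost per called base, where same-direction overlaps exceeded independent lists as well. Over all regions called between Res and Sen the balance was slight. Of these calls, 55.4% in H3K27ac and 57.9% in H3K9ac had the opposite sign after knockdown. Per called base the shares were 49.9% and 61.0%. Of 11679 regions tested in both comparisons of H3K27ac, 83 were higher in Res and lower after knockdown against 41.3 for independent lists, and 31 were lower and then higher against 15.6. Same-direction overlaps were 17 against 16.8 and 38 against 38.3. In H3K9ac (10149 regions) the opposite overlaps were 213 against 135.9 and 121 against 67.3, and the same-direction ones 49 against 73.5 and 124 against 124.4. The changes correlated weakly over regions, which are not independent replicates (r = -0.111 and rho = -0.107 in H3K27ac, -0.204 and -0.169 in H3K9ac; 10 simulations of unchanged groups gave -0.0029 and -0.0038). These comparisons share no library, so a simulated value near 0 was given in advance and does not weigh for the correlations. The H3K27ac correlation was -0.053 after removing chromosome medians, -0.021 per called base and -0.075 without the first control library. Per called base in H3K27ac, the opposite overlaps were 66 against 54.6 and 20 against 12.5. The same-direction ones were 21 against 13.6 and 67 against 50.2. With window medians removed in H3K27ac, the opposite overlaps were 19 against 7.4 and 8 against 3.4. The same-direction ones were then 9 against 3.2 and 12 against 7.9. After removing window medians in H3K9ac, the opposite overlaps were 82 against 35.5 and 39 against 15.6. Of the same-direction ones, 13 were higher in both against 16.2, and 52 lower in both against 34.0.

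Res_Ctrl, the background for the knockdown, was itself far from Res. H3K27ac was higher in Res_Ctrl at Pdxk (2.78 ± 0.23), the region of Slc39a4 and Vps28 (2.38 ± 0.15), the tetraspanin Cd53 (2.36 ± 0.17), the water channel Aqp1 (2.16 ± 0.14) and Slc4a9 (2.09 ± 0.15). It was lower at Clca3a1 (-3.22 ± 0.14), the region of Pus10 and the NF-kB subunit Rel (-2.58 ± 0.12), cyclin D2, Ccnd2 (-2.41 ± 0.16), Sparc (-2.38 ± 0.11) and Mndal (-2.19 ± 0.17). H3K9ac was 7.77-fold higher at Itga2 (2.96 ± 0.08, adjusted p = 4.5e-10) and lower at Ccnd2 (-2.11 ± 0.14) and Fn1 (-1.66 ± 0.10). In H3K27ac 2317 of 13895 regions rose and 2825 fell, and in H3K9ac 2191 of 10300 rose and 2309 fell. Gained and lost regions numbered 1601 and 1395, and 438 and 342. Without the first or the third Res_Ctrl library 1279 and 1319 H3K9ac regions were gained or lost. Csf1, with 1758 ± 185 tags, and Mtap, with 487 ± 60.3, were among the genes with an H3K27ac peak in Res_Ctrl and none in Res, with the doubt about the H3K27ac lists of Res at Csf1 given above.

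None of the list calls that follow held with an estimated correlation. Epithelial markers passed as higher in Res_Ctrl than in Res (7 of 10 rose and 0 fell in H3K27ac, camera adjusted p = 0.00062; 9 of 11 and 0 in H3K9ac, 3.1e-05; 10 of 11 adjusted over the list alone), with Krt7 at 1.14 ± 0.17 and 1.30 ± 0.09. The stress list passed as lower (0 of 18 rose and 9 fell, 0.0012; 3 of 21 rose and 14 fell, 3.1e-05), with Asns at -1.38 ± 0.21 and -1.45 ± 0.13. Hypoxia and glycolysis genes passed as higher (10 of 20 rose and 2 fell, 0.0077; 13 of 19 and 2, 0.025). After removing window medians neither passed (0.054 and 0.082), nor that in H3K9ac after removing chromosome medians (0.052), in ranges over alternatives from 0.0043 to 0.55 and from 0.0028 to 0.28. Higher too was Pdk1 in H3K27ac (0.81 ± 0.14; 0.12 per called base, below the threshold). Neural and glial markers passed as higher in H3K27ac (2 of 3, 0.0023; Nes 1.57 ± 0.21). Mesenchymal markers passed as lower (1 of 13 rose and 4 fell, 0.020), with a median of 0.07 and a mean of -0.47, so that median and test differ in sign. Without the first Res_Ctrl library the adjusted p was 0.11, in a range over alternatives from 0.0026 to 0.55. It was 0.53 per called base and 0.064 under the intensity trend offset. The calls were lost with an estimated correlation (adjusted p = 0.311, 0.553, 0.553, 0.311 and 0.553 with an estimated correlation in H3K27ac for the lists in this order, and 0.168, 0.276 and 0.276 in H3K9ac). This comparison uses the same Res libraries as Res against Sen, so that part of any opposite movement of the comparisons may come from the shared libraries.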

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

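The intensity trend, the chromosome and 5 Mb window offsets and the comparison of Res_Ctrl with Sen were chosen after seeing the data; the other settings were not. The 54 counts, correlations and other summary values had 460 values under alternatives, of which 345 stayed within the allowed range and 115 moved. The range was 1.5 times for a count and 1 SD between libraries for a difference in peaks per library. The H3K27ac difference in peaks between Res and Sen, 453 and not separated, changed sign within that SD: it was -344.7 without the first Res library and -1720.8 without the first Sen library, in a range up to 2025.2. The cause was not tested for any of them. A mean of at least 50 tags removed no region, so it says nothing about stability. Tags per called base shrink changes by construction, because the called width grows with the tags. Peak lists hold no counts outside peaks, so regions without a peak in 1 library could not be tested.

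At a caller threshold of 1e-10, 613 H3K27ac regions were lost in Res against Sen. After knockdown 1202 H3K27ac and 900 H3K9ac regions were gained, 11 and 0 were lost, and tags fell in 258 H3K27ac regions. With equal numbers of peaks the knockdown gained 427 and lost 221 H3K27ac regions and gained 194 and lost 129 H3K9ac regions, and Res gained 739 and lost 930 H3K9ac regions against Sen.

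With the chromosome offset, 1327 H3K27ac and 1973 H3K9ac regions rose in Res against Sen. After knockdown 235 fell in H3K27ac, and 163 rose and 365 fell in H3K9ac. Changed regions numbered 2916 between Res_Ctrl and Res in H3K9ac, and 986 and 2107 between Res_Ctrl and Sen in H3K27ac and H3K9ac. In H3K9ac 5 lists passed for Res against Sen and 1 for the knockdown, and the correlations of Res against Sen with the knockdown were -0.053 and -0.142. With the 5 Mb window offset, 1146 H3K27ac regions rose, and 1807 H3K9ac regions rose and 1732 fell, in Res against Sen. After knockdown 118 rose and 153 fell in H3K27ac, and 142 and 290 in H3K9ac. Between Res_Ctrl and Res 3259 and 2605 regions changed, and between Res_Ctrl and Sen 813 and 1918. The lists that passed were 2 for the knockdown in H3K27ac, 7 for Res against Sen in H3K9ac and 1 for the knockdown in H3K9ac, and the correlations were -0.062 and -0.158.

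DESeq2 called 376 H3K27ac regions higher after knockdown, and the replicate block gave 502 higher and 939 lower. With all 12 libraries in the fit, 51 were higher and 119 lower. Per called base 396 H3K27ac regions were higher and 916 lower after knockdown. In H3K9ac 1 list then passed in each main comparison, and the correlations were -0.021 and -0.227. Directions reversed per called base at Them6 and Psca (0.023) in Res against Sen. After knockdown they did so in H3K27ac at Acsl3 (-0.055), Efnb1 (-0.018), Flt1 (-0.15), Phyh (-0.077), Vcam1 (-0.35) and the region in Itgb3 (-0.024). In H3K9ac they did so at Acsl3 (-0.020), Vegfa (0.025), Sqstm1 (-0.15), Hip1r (-0.45) and Cfap410 (-0.078). Of these reversals only those of Vcam1 and Hip1r passed the threshold.

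With an estimated correlation 0 lists passed by camera in Res against Sen, the knockdown, and Res_Ctrl against Res, in either mark. The rotation test fry passed 1 list for the knockdown in H3K27ac and 0 in H3K9ac, 12 for Res against Sen in H3K9ac and 10 for Res_Ctrl against Res in H3K9ac.

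Leaving out 1 library gave ranges, in H3K27ac, of 976 to 2955 lost and 1122 to 2586 lower regions for Res against Sen. For the knockdown they were 1278 to 3495 gained, 29 to 74 lost, 41 to 305 higher and 122 to 566 lower. For Res_Ctrl against Sen they were 1010 to 1993 gained or lost and 1251 to 3436 changed. In H3K9ac the knockdown had 943 to 2884 gained, 5 to 25 lost, 79 to 509 higher and 224 to 611 lower. Gained or lost regions ranged from 863 to 1319 for Res_Ctrl against Res and from 1042 to 2449 for Res_Ctrl against Sen. Lists passing ranged from 1 to 2 for Res against Sen and 1 to 4 for the knockdown in H3K27ac, and in H3K9ac from 1 to 6 for the knockdown and 3 to 5 for Res_Ctrl against Res. The correlations ranged from -0.135 to -0.075 and from -0.213 to -0.177, and Vcam1 after knockdown from -0.10 to 0.68.

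Of 168 gene results, 131 kept their call per called base, 24 lost the threshold, 1 gained it and 12 reversed. With DESeq2 164 kept it, with the chromosome offset 154 and with the 5 Mb window offset 150. Leaving out 1 library, with regions merged and picked again, kept 907 of 1003 calls, lost 95 and reversed 1. After knockdown 5 of 21 genes in H3K27ac and 10 of 27 in H3K9ac kept their call in every setting, against 29 of 37 and 41 of 50 for Res against Sen.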

Other observations

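The comparison of Res_Ctrl with Sen and the search for strong H3K9ac peaks without H3K27ac were chosen only after the results were seen. Res_Ctrl against Sen had H3K27ac higher at the processing enzyme Cpe (2.13 ± 0.11, 3 libraries against 3), the signalling inhibitor Socs2 (1.78 ± 0.12) and Atp2c2 (1.74 ± 0.16), and lower at Zfp532 (-2.52 ± 0.12), Gpc6 (-1.79 ± 0.19) and the adhesion molecule Vcam1 (-1.52 ± 0.12). H3K9ac was higher at Igf2bp1 (2.45 ± 0.07), Mtap (2.38 ± 0.09) and the transcription factor Jun (1.80 ± 0.08), and lower at Zfp532 (-2.11 ± 0.09) and Hip1r (-1.67 ± 0.09). Of 13130 H3K27ac regions 1281 rose and 959 fell, and of 10980 H3K9ac regions 2067 and 1653. Calls in H3K27ac numbered 3436 without the first Sen library, 1427 without the third, and 1408 and 1251 without the second and the third Res_Ctrl library. The interferon genes Bst2, Jak1 and Stat2 gained H3K27ac peaks (Fisher's exact test, adjusted p = 0.0174). Jak1 lies in the run of H3K27ac regions missing in Sen (chromosome 4, 100775686 to 102571689). Bst2 lies on chromosome 8, whose H3K27ac median was 0.63 in this comparison, and Stat2 had only 53.7 ± 17.0 tags. The test therefore cannot tell a gain of interferon genes from shifts of chromosomes or segments. Cdkn2a, present in Sen with 798 ± 431 H3K9ac tags (n = 3), had no H3K9ac peak in Res_Ctrl or in Res.

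Of 5971 strong H3K9ac regions in Res, those in all 3 libraries with tags above the median, 2 had no H3K27ac peak in any Res library. Both lay at Csf1, at 107736148 to 107745357 (835 ± 21.0 tags, n = 3) and 107755191 to 107761487 (956 ± 91.8) of chromosome 3. Sen had 1 such region of 7331, at Eif4enif1 and Sfi1, Res_Ctrl 0 of 5607 and Res_shFabp7 0 of 7800. The cause was not tested. Peaks on chromosome Y were called only in H3K9ac of Sen, with 1, 2 and 3 peaks per library.

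Tag counts moved along whole chromosomes in both marks; the test of copy number was chosen only after the result was seen. A difference in depth or enrichment that changes with signal strength was argued against as the whole cause, since the mean absolute chromosome median under the intensity trend offset was 98.5% of the unadjusted one. That offset is a weak test, as it left 164 of 168 gene calls as they were. Per called base, which shrinks changes by construction, the mean was 0.065 against 0.127, so a partial contribution stays open. A test of a few strong regions per chromosome decided nothing: for 100% of the 38 chromosome medians of 0.2 or more both quartiles moved by at least 0.5 of the shift of the median, but these chromosomes were chosen for a shifted median, which a few regions hardly move. DNA copy number that differs between the lines stays open and may explain the shifts. The medians of both marks correlated over 20 chromosomes with r of 0.957 or more in all 4 comparisons. Any cause that acts along whole chromosomes in both marks would give this, so the correlation does not favour copy number over other causes. Copy number itself was not measured here, and the inputs were not used here.

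Peaks gained far outnumbered peaks lost after knockdown; the test of tag totals was chosen only after the result was seen. Weak sites that just passed the caller's threshold may account for part of this, because gained peaks had a median percentile by tags of 19.9 in H3K27ac and 13.9 in H3K9ac within their own libraries. More tags in the knockdown libraries may add to it: in regions called in all 6 libraries, the lowest knockdown total was 1.07 times the highest control total in H3K27ac and 1.04 times in H3K9ac. Sites made accessible by the knockdown alone are left undecided, since 65.4% of gained H3K27ac regions and 71.1% of gained H3K9ac regions overlapped a peak of a Res or Sen library. A biological effect of Fabp7 on the number of acetylated sites stays open and cannot be told apart from the yield of the libraries, which lies along the same groups.

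Tag counts differed between Res_Ctrl and Res in 5142 H3K27ac regions, against 3808 between Res and Sen, and in 4500 H3K9ac regions, against 6093; the tests on Sen cells and on the chromosome 4 segment were chosen only after the result was seen. Whether Res_Ctrl libraries were made from the same cells as the Sen libraries is left undecided. The chromosome 8 medians of any Res_Ctrl and any Sen library lay at least 0.506 apart, which goes against it. Chromosome 8 was picked for the largest shift, and 4 of 20 chromosomes passed 0.2 in both marks. A shift picked in this way cannot settle the question. Other values place Res_Ctrl near Sen: 2240 H3K27ac regions changed between them, a pair of their libraries shared on average 72.4% of H3K27ac regions, against 67.8% for Res_Ctrl and Res (75.9% against 76.9% in H3K9ac), and both hold peaks in the chromosome 4 segment. A share of Sen cells in the Res_Ctrl libraries was not tested. Shifts of whole chromosomes alone were argued against. Calls under the 5 Mb window offset numbered 63.4% of the unadjusted total in H3K27ac and 57.9% in H3K9ac. These percentages compare totals and do not follow single calls. Shifts of segments shorter than a window, or in windows with fewer than 10 regions, are not removed by this offset and stay open. Res libraries may come from cells that lack a segment of chromosome 4 which Res_Ctrl cells hold. This cannot account for the regions with changed tag counts, which need a peak in every library, and bears only on gained and lost regions. Res_Ctrl libraries had at least 19 H3K9ac peaks in that segment and Res libraries 0. The segment was found from missing H3K27ac peaks, and 95.0% of H3K9ac peaks overlapped one, so this result was nearly given in advance. Whether the cells lack the segment stays open. Effects of the hairpin vector, selection and time in culture were not tested.

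Counts of other splits of the 6 libraries were chosen only after the result was seen for tags and for gained or lost regions, and not for lists. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split was 1 of them. Of changed regions the real split gave 3808, 626, 5142 and 2240 in H3K27ac (Res against Sen, knockdown, Res_Ctrl against Res, Res_Ctrl against Sen) and 6093, 895, 4500 and 3720 in H3K9ac, and the highest other split 0 by edgeR in each. Gained or lost regions were 2583, 1212, 2996 and 857 in H3K27ac, with 405, 618, 204 and 475 in the highest other split. In H3K9ac they were 2596, 942, 780 and 999, with 50, 366, 201 and 329. Lists called were 2, 4 and 5 in H3K27ac for the comparisons in this order without the last, with 3, 3 and 4 in the highest other split, and 3, 2 and 3 in H3K9ac, with 2, 3 and 4. As many lists came from 3 of the 10 splits for Res against Sen in H3K27ac and for the knockdown and Res_Ctrl against Res in H3K9ac, and from 1 in the others.

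Changes of Res_Ctrl against Sen were set beside those of Res against Sen, which use the same Sen libraries; this was chosen only after the results were seen. In H3K27ac r was 0.369 and the covariance 0.0801, against 0.509 and 0.0147 in simulations of unchanged groups, and 449 regions were higher in both against 171.5 for independent lists. In H3K9ac r was 0.446 and the covariance 0.0632, against 0.418 and 0.0041, with 1052 regions against 538.8. Part of the excess over independent lists may come from the shared Sen libraries. With the chromosome offset, 986 H3K27ac and 2107 H3K9ac regions changed between Res_Ctrl and Sen.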
